A study of Mus musculus with 8 samples.

How the data were processed

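Gene expression was measured in primary hepatocytes of male C57BL/6J mice, cells taken from the liver by perfusion with collagenase and kept in culture. Wells were either left as controls or given 500 µM metformin, a glucose-lowering biguanide drug, for 24 h, with 4 wells in each group. Per the labels' protocols, total RNA was extracted with TRIzol, labelled with biotin and read on an Illumina mouse bead array, on which each probe reports the brightness of 1 transcript sequence. The labels do not say whether the wells of a group came from different animals or cell isolations, so the p-values measure only the spread between these samples, which may be technical.

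The values were the log2 intensities deposited by the authors, with 1 column per array, 16304 probes and 0 missing values. Per the submitters' processing notes limma 3.26.9 and R 3.2.3 were used, with no role given for either. The background correction, the normalization method and any filter on probes were not given in the sources used here. The deposited values lay between 4.16 and 14.4, and the array medians differed by at most 0.00080 log2 units. At any rank the sorted values of an array differed from those of the first array by at most 0.089 log2 units, so the arrays had been brought to nearly the same distribution before deposition and were used without a further normalization. Detection p-values were not used here, so that how far a dim probe stood above background is unknown. Values near the lower end of the range can therefore understate a change. The number of arrays limits the precision.

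Probes were named through the platform's annotation table. Of the 16304 probes, 15301 had 1 gene symbol, 0 had several and 1003 are unnamed here. Symbols were brought up to date through the Entrez number in the RefSeq gene table of the mouse assembly GRCm38.p6, which held the genes of 15294 of the named probes, and the other 7 kept the platform's symbol. No coordinates of that assembly were used, since the array's own build was not given in the sources used here. Each gene was represented by its brightest probe over the 8 arrays, which gave 10944 genes, of which 3008 had more than 1 probe. Where the probes of a named gene moved in opposite directions, this is stated beside the gene. The genes of near-identical copies, such as those of histone H2A, cannot be told apart with certainty by their probes and are reported as uncertain.

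The design holds 1 comparison, metformin minus control. A linear model was fitted to each gene with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 8 arrays. The two-sided p-values were adjusted over the 10944 genes by the Benjamini-Hochberg method, with an adjusted p under 0.05 as the threshold. Unless stated otherwise, a value after ± is the standard error of the log2 fold change, and adjusted p refers to this model. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 33 lists, of which 28 hold genes of a pathway or process and 5 hold markers of other liver cell types. The camera test was repeated with a correlation estimated from the arrays, and fry was run as a test of whether the members moved, on balance, in 1 direction. For each list the members past the threshold were counted both with the adjustment over all genes and with the p-values adjusted over the list alone. The lists, the model, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is stated to have been made later.

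The genes named were chosen by a rule with 3 parts. The first part took the 12 higher and the 12 lower genes with the largest change among those past the threshold whose 4 metformin arrays all lay on 1 side of the 4 control arrays, without predicted loci. The next part took from each list up to 4 members with the smallest adjusted p among those past the threshold, or the 2 members with the smallest p where none passed. The last part took 30 genes of hepatic glucose, lipid, stress and inflammatory regulation whatever their values. Of these 30, 13 are not analysed here, and the other 17 are reported. Genes named outside this rule were chosen after their values were seen, and each is marked where it appears.

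Whether equal replicate numbers pair the wells was checked from the deviations of each array from its group mean. The correlations of the same-numbered control and metformin arrays were 0.32, 0.28, 0.15 and 0.23. Their mean of 0.245 was the highest of the 24 possible pairings. All 4 were over 0.1, so the numbers were taken to pair the samples, on the basis of the data alone. The labels do not say what a number marks. The main model, fixed beforehand, holds no term for the number, so its p-values ignore this pairing. A fit with the replicate number as a block was therefore run, and its value is given beside a result where it changed the call.

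The model was tested on simulated arrays with the means and variances of the 10944 genes for this comparison, in which 200 genes were changed, in 5 simulations. It recovered 18% of changes of 0.5 log2 units, 83.2% of changes of 1, 97.6% of changes of 1.5 and 99.6% of changes of 2, and 4.48% of the calls were false. Without any change it made 0 calls. A list shifted by 0.5 log2 units was called in 5 of 5 simulations. These simulated arrays held no pairs and no correlation between genes.

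The alternatives were quantile, median and cyclic loess normalization, leaving out the lowest 25% or the lower 50% of genes, the mean of a gene's probes, every probe by itself, eBayes with trend and robust settings, array weights, the replicate block, a minimum change of 1.5-fold, an offset of 16 on the linear scale, and leaving out each array in turn. A fit with the endothelial marker score as a covariate, and counts of list members without each array, were added after seeing the data.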

Results

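Transcripts of 8 cultures of primary mouse hepatocytes were measured, 4 without and 4 with metformin at 500 µM for 24 h, on 1 array each. The median intensity of every array was 6.48 log2 units. Correlations across genes ranged from 0.972 to 0.987 between control arrays, from 0.978 to 0.990 between metformin arrays and from 0.961 to 0.983 between the groups. The first principal component, with 37.9% of the variance, placed all 4 control arrays on 1 side and all 4 metformin arrays on the other.

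The comparison asks which transcripts of hepatocytes differ after a day of metformin. Of 23 measured cell cycle genes 15 fell, among them Rrm2, the small subunit of ribonucleotide reductase, which fell by 2.55 ± 0.25 log2 units (n = 4 per group), and Mcm3 and Mcm5, subunits of the replicative helicase. Of 29 lysosome and autophagy genes 8 rose, among them Ctsd, which encodes the protease cathepsin D (1.88-fold, at a probe dim for its list). Of 18 cholesterol genes 5 rose, such as Fdps, farnesyl diphosphate synthase (2.53-fold). These 3 lists passed camera, but had an adjusted p = 0.207, 0.207 and 0.507 with an estimated correlation. Calr, an endoplasmic reticulum chaperone, and Myc fell. Of 10 gluconeogenesis genes 3 rose, Gpt and, at a dim probe, Pcx among them.

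Across the 10944 genes, 363 were higher and 377 lower with metformin at an adjusted p under 0.05, and 2607 had an unadjusted p under 0.05. Of the genes past the threshold, 76 of the higher and 110 of the lower changed at least 2-fold. All 4 metformin arrays lay above all 4 control arrays for 843 genes and below them for 828, which together is 15.3% of the genes, where chance gives 2.86%. The counts depended on single arrays. They were 128 higher and 129 lower without control replicate 2, 109 and 109 without control replicate 3, and 173 and 155 without control replicate 4. Without metformin replicate 2 they were 79 and 100, and without metformin replicate 3 they were 70 and 104. They were 401 and 393 without control replicate 1, 378 and 349 without metformin replicate 1, and 304 and 312 without metformin replicate 4. Each of these fits also held fewer samples. Array weights gave 606 higher and 583 lower. The replicate block, which takes up the pairing, gave 483 higher and 446 lower. It shared 613 genes with the fit without it, lost 127 and gained 316.

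The largest rise among the named genes was that of Bex2, from 8.73 ± 1.05 to 11.15 ± 0.62 log2 units (mean ± SD, n = 4; 5.35-fold; limma adjusted p = 0.0245). Hr, which encodes the transcriptional corepressor hairless, rose from 6.14 ± 0.29 to 8.52 ± 0.53 (5.19-fold, limma adjusted p = 0.00599). The changes of the single probes ran from 1.33 to 2.42 for Bex2 and from 1.27 to 2.38 for Hr. Plin4, a coat protein of lipid droplets, rose by 1.93 ± 0.34, and Grem1, an antagonist of bone morphogenetic proteins, by 1.80 ± 0.17. Among the same 12 were Vil1 (the actin-binding protein villin, 1.70 ± 0.30), Cldn1 (claudin 1 of tight junctions, 1.66 ± 0.24) and Anpep (aminopeptidase N, 1.56 ± 0.15). The other large rises were those of Ankrd23 (1.83 ± 0.26), Gipc2 (1.77 ± 0.25), Bhmt2 (1.70 ± 0.26) and Nudt18 (1.59 ± 0.20). Clec2e rose by 2.12 ± 0.34 with its brighter probe, while its other probe gave -0.14, and the mean of its probes 0.99. The adjusted p of these 12 genes lay between 0.00581 and 0.0245. In the 8 fits that left out 1 array, Bex2 passed the threshold in 4, Plin4 in 6, Vil1 in 7 and the other 9 in all.

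Among the lower genes, Rrm2 fell from 9.13 ± 0.41 to 6.58 ± 0.44 log2 units (mean ± SD, n = 4; limma adjusted p = 0.00581). Its other probe gave a change of -1.54. Ctcfl, a paralog of the chromatin insulator CTCF, changed by -2.51 ± 0.52, and the tetraspanin gene Tspan8 by -2.09 ± 0.41. Pclaf, which binds the replication clamp PCNA (-1.95 ± 0.36), the mitotic kinase Plk1 (-1.82 ± 0.42) and Kif23, a kinesin of cytokinesis (-1.80 ± 0.41), also fell. Fbp2, the muscle type of fructose bisphosphatase, fell by 1.77 ± 0.25 to a level near the lower end of the scale. Probes of the histone genes H2ac22 (-2.14), H2ac10 (-2.03), H2ac15 (-1.78) and H2ac24 (-1.76) were lower, but these near-identical copies may share signal and are uncertain as single genes. The adjusted p of the 12 lower genes, Calr included, lay between 0.00581 and 0.0374. In the fits that left out 1 of the 8 arrays, Plk1 and Kif23 passed the threshold in 2, Calr in 3, Ctcfl and H2ac15 in 4, Tspan8 in 5, Pclaf in 7 and the other 5 in all.

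**Figure D1:**
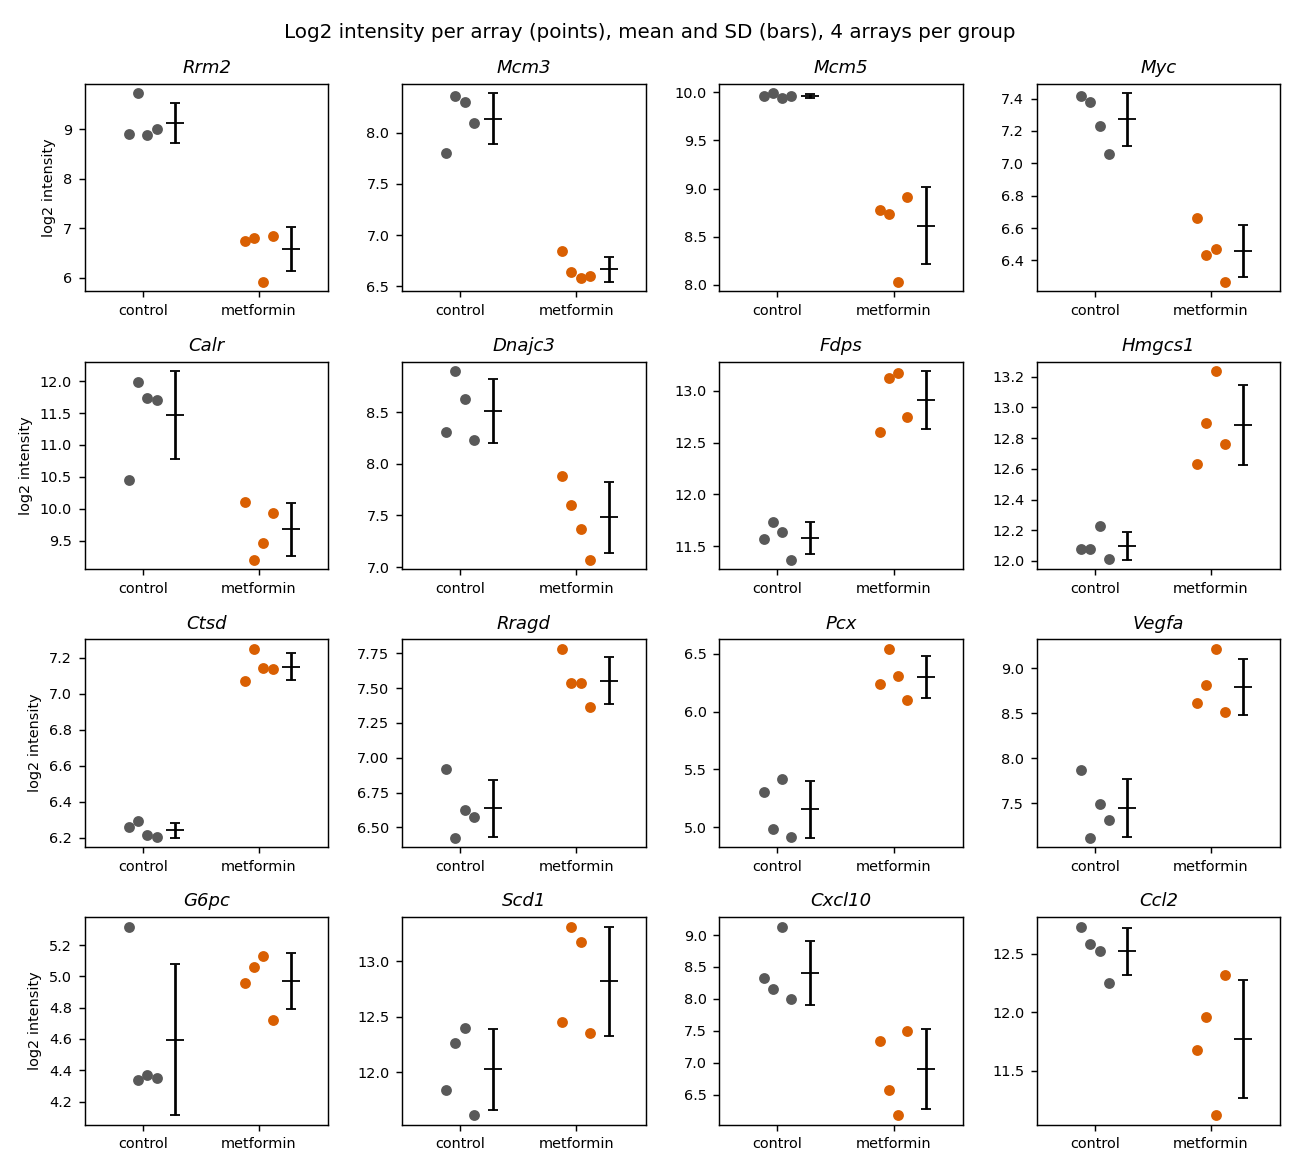
Log2 intensity (y axis) of 16 genes in the 4 control (grey) and 4 metformin (orange) arrays; points are arrays, bars the mean with its SD, and each panel has its own axis range. Rrm2 fell from 9.13 ± 0.41 to 6.58 ± 0.44 and Ctsd rose from 6.24 ± 0.041 to 7.15 ± 0.074 without overlap of the groups, whereas the 2 groups overlap for G6pc, Scd1 and Ccl2.

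Cell cycle genes formed the list with the largest median change of the 33. All 23 measured members had lower values with metformin, and 15 of them fell past the threshold over all genes, or 21 adjusted over the list alone. The median change was -1.17 log2 units (camera adjusted p = 4.71e-17; adjusted p = 0.207 with an estimated correlation), and -0.75 with the mean of each gene's probes. Besides Rrm2, the genes with the smallest p were Mcm3 (-1.47 ± 0.14, adjusted p = 0.00581), Rrm1, the large subunit of ribonucleotide reductase (-1.11 ± 0.15, adjusted p = 0.00855), and Mcm5 (-1.35 ± 0.18, adjusted p = 0.00867). Control replicate 2 stood above the other control arrays for this list, with a mean deviation of 0.78 against 0.50 to 0.54. The number of members past the threshold was 8 without control replicate 3, and 9 without control replicate 2 or 4 or metformin replicate 2. Mcm3, Rrm1 and Mcm5 passed in all 8 fits without 1 array.

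Members of the endoplasmic reticulum chaperone list were also lower. Of 16 measured, 2 fell and 0 rose, over all genes as well as adjusted over the list alone, and 14 had lower values. Calr, the chaperone calreticulin, went from 11.47 ± 0.69 to 9.67 ± 0.42 log2 units (mean ± SD, n = 4; limma adjusted p = 0.0185), and Dnajc3, a cochaperone of the endoplasmic reticulum, changed by -1.03 ± 0.20. The median change of the list was -0.35 (camera adjusted p = 0.00163; adjusted p = 0.207 with an estimated correlation). In the ribosome biogenesis list 4 of 21 measured members fell and 0 rose, with the same numbers adjusted over the list alone. These were the transcription factor gene Myc (-0.81 ± 0.13), Bop1, a factor in the maturation of the large ribosomal subunit (-0.72 ± 0.12), and Polr1e (-0.95 ± 0.21) and Polr1a (-0.47 ± 0.11), subunits of RNA polymerase I. The list's median was -0.14 (camera adjusted p = 0.00342; adjusted p = 0.60 with an estimated correlation), but -0.21 without control replicate 1, -0.23 without control replicate 4, -0.21 without metformin replicate 4 and -0.24 with the lowest 25% or the lower 50% of genes left out. The probes of Polr1a disagreed, from -0.83 to 0.25, and with the replicate block its adjusted p was 0.0571. The number of chaperones past the limma threshold was 0 without control replicate 2 or 3 or metformin replicate 2 or 3, and 1 without control replicate 4, against 9 at an unadjusted p under 0.05 with all arrays. That of ribosome biogenesis genes was 2 without control replicate 2, 3 or 4 or metformin replicate 1, 2 or 3. Polr1e and Polr1a passed in 2, Dnajc3 in 4, and Myc and Bop1 in all of the 8 fits without 1 array, with adjusted p of up to 0.122.

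Cholesterol synthesis genes were higher with metformin. Of 18 measured members, 5 rose and 0 fell over all genes, or 10 higher and 1 lower adjusted over the list alone, and the median change was 0.49 (camera adjusted p = 0.00139; adjusted p = 0.507 with an estimated correlation). Fdps rose from 11.58 ± 0.15 to 12.91 ± 0.28 log2 units (mean ± SD, n = 4; limma adjusted p = 0.00642). Hmgcs1, which makes HMG-CoA (0.78 ± 0.14), Pmvk, phosphomevalonate kinase (0.77 ± 0.18), and Srebf2, the transcription factor that drives the pathway (0.51 ± 0.11), rose as well, as did Sqle, squalene epoxidase, chosen after its value was seen (adjusted p = 0.0426, or 0.0588 with the replicate block). The lower member was Insig1, chosen after its value was seen, at -1.17 ± 0.30 (adjusted p = 0.0503, or 0.0337 with the replicate block), with probes that moved in opposite directions. With the replicate block 8 members were higher and 1 lower, and the number past the threshold was 1 without metformin replicate 2, 2 without control replicate 2 or 4 or metformin replicate 3, and 3 without control replicate 3. Pmvk, Srebf2 and Fads1 passed in 3, Hmgcs1 in 7, and Fdps in all of the 8 fits without 1 array, with adjusted p of up to 0.104. In the fatty acid and triglyceride synthesis list 1 of 18 measured members rose over all genes, Fads1, a fatty acid desaturase (0.58 ± 0.13), or 2 higher and 0 lower adjusted over the list alone, with Slc25a1 chosen after the values were seen and past the threshold over all genes with the replicate block at adjusted p = 0.0267 (median 0.11, camera adjusted p = 0.260). With the block 4 were higher. Scd1, stearoyl-CoA desaturase, had a change of 0.80 ± 0.26 (adjusted p = 0.0984, or 0.0167 with the replicate block, and 0.0167 to 0.239 over the alternatives). Acaca, acetyl-CoA carboxylase (-0.23 ± 0.38), and Srebf1 (0.042 ± 0.19) did not pass.

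In the lysosome and autophagy list 8 of 29 measured members rose and 0 fell over all genes, or 9 and 0 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.00139; adjusted p = 0.207 with an estimated correlation). Ctsd went from 6.24 ± 0.041 to 7.15 ± 0.074 log2 units (mean ± SD, n = 4; limma adjusted p = 0.00599). Its probe was dim for the list, whose median level was 9.14. Hexa, a subunit of the lysosomal enzyme hexosaminidase A, rose by 0.72 ± 0.12. Rragd (0.92 ± 0.14), a Rag GTPase that tethers mTORC1 to the lysosome, and Fnip1 (0.71 ± 0.15), a partner of folliculin, rose too. The 6 autophagy members, chosen after their values were seen, did not pass, and their difference from the other members was not tested. Ulk1, a kinase that starts autophagy, had a change of -0.63 ± 0.27 (adjusted p = 0.186, or 0.0324 with the replicate block), Gabarapl1 one of -0.44, Map1lc3b -0.26, Wipi1 -0.21, Uvrag -0.075 and Sqstm1 -0.025. With the block 8 members were higher and 1, Ulk1, lower. The number past the threshold was 3 without control replicate 2 or 3 or metformin replicate 2 or 3, 4 without control replicate 4, and 5 without control replicate 1 or metformin replicate 4. Fnip1 passed in 3, and Ctsd, Hexa and Rragd in all of the 8 fits without 1 array, with adjusted p of up to 0.0835. The sinusoidal endothelial markers also had a positive median, 0.49, in this comparison.

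**Figure D2:**
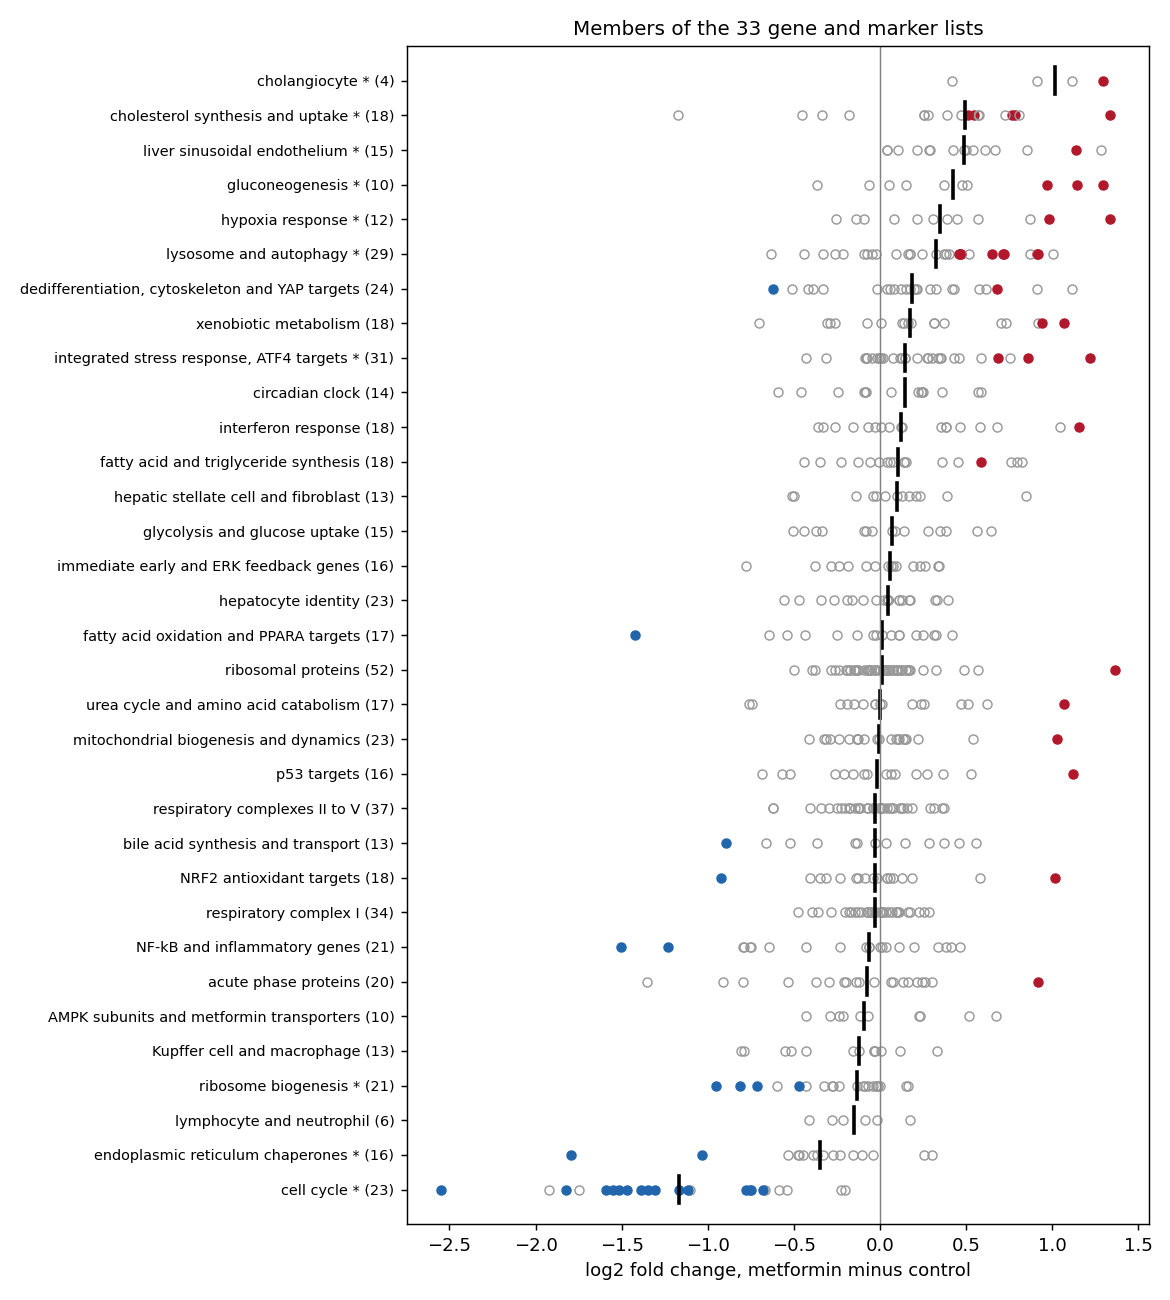
Log2 fold change, metformin minus control (x axis), of each measured member of the 33 lists (y axis, number measured in parentheses); filled red and blue points passed the threshold over all genes, open points did not, black bars are list medians and asterisks mark lists past the camera threshold. The medians run from -1.17 for the cell cycle to 1.01 for the 4 cholangiocyte markers.

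Gluconeogenesis genes had a median change of 0.43 (camera adjusted p = 0.0274; adjusted p = 0.60 with an estimated correlation), or 0.27 with the offset of 16. Of 10 measured, 3 rose and 0 fell, with the same numbers adjusted over the list alone. These were Pcx, pyruvate carboxylase (1.15 ± 0.15), Gpt, alanine aminotransferase (0.97 ± 0.19), and Creb3l3, a liver transcription factor of the fasted state (1.29 ± 0.30), whose groups overlapped. G6pc had a change of 0.37 ± 0.22 at dim levels (adjusted p = 0.351, but 0.0316 without control replicate 1, and 0.0316 to 0.549 over the alternatives), Fbp1 one of -0.37 ± 0.20 and Ppargc1a one of 0.15 ± 0.34, and none of them passed. The list's call was lost with the replicate block (adjusted p = 0.0538), without metformin replicate 1 (0.0566) and without metformin replicate 3 (0.0613), and over the alternatives its adjusted p was 0.00392 to 0.236. Creb3l3 had an adjusted p of 0.0515 with the block. The number of members past the threshold was 1 without control replicate 2 or 3 or metformin replicate 3. Creb3l3 passed in 2, Gpt in 4, and Pcx in all of the 8 fits without 1 array, with adjusted p of up to 0.114.

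Other lists of energy metabolism held few changes. Among glycolysis genes 0 of 15 passed in limma over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (median 0.068, camera adjusted p = 0.812). Pkm had a change of -0.50 ± 0.18 and Hk2 one of 0.64 ± 0.24, and Pklr one of 0.28 ± 0.16. Pkm passed with the replicate block (adjusted p = 0.0434, and 0.0434 to 0.293 over the alternatives), and Hk2 without control replicate 1 (adjusted p = 0.0333, and 0.0333 to 0.288 over the alternatives). Of 17 genes of fatty acid oxidation and PPARA targets, only Angptl4, an inhibitor of lipoprotein lipase, passed in either adjustment, and it fell by 1.43 ± 0.24 (list median 0.014, camera adjusted p = 0.676). Pdk4, a kinase of pyruvate dehydrogenase, had a change of -0.044 ± 0.20. In respiratory complex I, 0 of 34 measured subunits passed in limma and 1 had an unadjusted p under 0.05 (median -0.030, camera adjusted p = 0.812), and the smallest p were those of Ndufb10 (-0.36 ± 0.14) and Ndufb4 (-0.39 ± 0.18). In complexes II to V, 0 of 37 passed and 5 had an unadjusted p under 0.05 (median -0.028, camera adjusted p = 0.525), with Cox7b at -0.62 ± 0.18 (adjusted p = 0.0691, but 0.0431 without metformin replicate 4, and 0.0375 to 0.162 over the alternatives) and Atp5g1 at -0.41 ± 0.14 (adjusted p = 0.107, and 0.0479 to 0.260 over the alternatives). Neither list had a member past the threshold when adjusted over the list alone. Mfn2, which fuses mitochondria, rose by 1.02 ± 0.18 and was the only 1 of 23 genes of mitochondrial biogenesis and dynamics past the threshold, also adjusted over the list alone (median -0.0047, camera adjusted p = 0.812). AMPK subunits and metformin transporters had 0 of 10 past it in either adjustment and 3 at an unadjusted p under 0.05 (median -0.093, camera adjusted p = 0.812), with Prkag2 at 0.68 ± 0.25, Prkab1 at -0.29 ± 0.11 and Prkaa2, a catalytic subunit of AMPK, at 0.52 ± 0.24. Mfn2 passed in 6, and Angptl4 in all of the 8 fits without 1 array, with adjusted p of up to 0.0520.

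Targets of the integrated stress response had 3 of 31 measured members higher and 0 lower, with the same numbers adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.0407; adjusted p = 0.606 with an estimated correlation). Vldlr, a lipoprotein receptor (1.22 ± 0.18, with probes from -0.35 to 1.30 and a mean of its probes of 0.67), Nupr1, a stress-induced nuclear protein (0.86 ± 0.13), and Ddit4, an inhibitor of mTORC1 (0.68 ± 0.17), rose. Atf4 itself (-0.019 ± 0.17), Ddit3 (0.22 ± 0.18) and Trib3 (0.35 ± 0.14) did not pass. Hypoxia response genes had 2 of 12 higher in both adjustments, the growth factor gene Vegfa (1.34 ± 0.20, adjusted p = 0.0120) and the glycolytic regulator Pfkfb4 (0.98 ± 0.21), with a median of 0.35 (camera adjusted p = 0.0337; adjusted p = 0.60 with an estimated correlation). Both lists lost their call with the replicate block (adjusted p = 0.0539 and 0.0538), as did Ddit4 (0.0515). The stress response list also lost it without control replicate 1 (0.122), control replicate 4 (0.0607), metformin replicate 2 (0.180) or metformin replicate 3 (0.0602), and the hypoxia list without control replicate 2 (0.0901) or metformin replicate 3 (0.0602). Over the alternatives the adjusted p was 0.0145 to 0.273 for the stress response list and 0.0143 to 0.0901 for the hypoxia list, in which the number of members past the threshold was 1 without control replicate 2 or 3 or metformin replicate 2 or 3. The stress response median was 0.24 without metformin replicate 1, 0.059 without metformin replicate 2 and 0.081 with the endothelial score as a covariate, and the hypoxia median 0.21 without control replicate 2. Ddit4 passed in 1, Pfkfb4 in 3, and Vldlr, Nupr1 and Vegfa in all of the 8 fits without 1 array, with adjusted p of up to 0.121.

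Inflammatory genes fell singly. Cxcl10, a chemokine induced by interferon (-1.50 ± 0.33), and the cytokine gene Il1b (-1.23 ± 0.28) were the 2 of 21 measured NF-kB and inflammatory genes past the threshold in both adjustments, and the list was not called (median -0.067, camera adjusted p = 0.0975, but 0.0297 without metformin replicate 4, and 0.0297 to 0.308 over the alternatives). The chemokine genes Cxcl1 (-0.79 ± 0.28, adjusted p = 0.118) and Ccl2 (-0.75 ± 0.23, adjusted p = 0.0869) did not pass, and with the replicate block 5 members, Cxcl1 among them (adjusted p = 0.0164, and 0.0164 to 0.273 over the alternatives), were lower. Without metformin replicate 1 Cxcl1 passed (adjusted p = 0.0361), and Ccl2 did so without metformin replicate 4 (0.0423, and 0.0423 to 0.174 over the alternatives). Crp, C-reactive protein, rose by 0.92 ± 0.20 as the only member past the threshold in both adjustments of 20 acute phase genes (median -0.077, camera adjusted p = 0.812), and Saa1 had a change of 0.24 ± 0.24. With the block 1 acute phase gene was lower as well. Among 18 interferon response genes Rsad2, an antiviral protein, rose by 1.15 ± 0.29 over all genes, and 0 passed in limma adjusted over the list alone against 3 at an unadjusted p under 0.05 (median 0.12, camera adjusted p = 0.282, but 0.0405 without control replicate 3, and 0.0405 to 0.812 over the alternatives). With the block 4 were higher. Rsad2 passed in 1, Il1b in 2, Cxcl10 in 3, and Crp in 4 of the 8 fits without 1 array, with adjusted p of up to 0.140.

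Hepatocyte functions changed in single genes. Abcb11, the bile salt export pump, fell by 0.90 ± 0.14 and was the only 1 of 13 bile acid genes past the threshold in both adjustments (median -0.028, camera adjusted p = 0.812). In the xenobiotic list the receptor gene Nr1i2 (PXR, 0.94 ± 0.16) and Cyp2b10 (1.07 ± 0.20, other probe 0.091, mean of the probes 0.58) rose among 18. Adjusted over the list alone 4 were higher and 0 lower, with Cyp2a5 and Ugt2b36 chosen after the values were seen. Both of these passed over all genes with the replicate block at adjusted p = 0.0153 and 0.0201. The list's median was 0.17 (camera adjusted p = 0.116, but 0.0202 without metformin replicate 4, and 0.0202 to 0.375 over the alternatives). This median ranged from 0.051 to 0.45 over the fits without 1 array. With the block 5 xenobiotic genes were higher and 1 lower. Hal, which degrades histidine, rose by 1.07 ± 0.25 as the only 1 of 17 genes of the urea cycle and amino acid catabolism, or 2 higher and 1 lower adjusted over the list alone, with Fah and Arg1 chosen after the values were seen (median -0.00052, camera adjusted p = 0.812). Of 23 hepatocyte identity genes 0 passed in limma in either adjustment and 1 had an unadjusted p under 0.05 (median 0.046, camera adjusted p = 0.954). Foxa2, a liver transcription factor, had a change of -0.47 ± 0.12 (adjusted p = 0.0542, but 0.0432 without control replicate 1, and 0.0281 to 0.144 over the alternatives), Rbp4 one of -0.34 ± 0.16 and Alb, at a dim probe, one of 0.39 ± 0.20. The dedifferentiation and cytoskeleton list had the actin gene Actg1 (0.68 ± 0.17) higher and Amotl2 (-0.62 ± 0.15) lower among 24, or 2 higher and 1 lower adjusted over the list alone, with Ccn2 chosen after the values were seen and past the threshold over all genes with the replicate block at adjusted p = 0.0406 (median 0.19, camera adjusted p = 0.183, but 0.0384 without metformin replicate 1, and 0.0384 to 0.967 over the alternatives), and with the block 4 higher and 1 lower. The probe of Actg1 was dim for its list, at 5.51 log2 units in control arrays, far below the list's median level. Actg1 and Amotl2 passed in 1, Hal in 3, Cyp2b10 in 5, Nr1i2 in 6, and Abcb11 in all of the 8 fits without 1 array, with adjusted p of up to 0.138.

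The remaining process lists were not called. Of 18 NRF2 targets Ftl1, ferritin light chain (1.02 ± 0.20), rose and Gclc, which starts glutathione synthesis (-0.92 ± 0.23), fell, or 2 higher and 1 lower adjusted over the list alone, with Taldo1 chosen after the values were seen and past the threshold over all genes with the replicate block at adjusted p = 0.0329 (median -0.030, camera adjusted p = 0.812). Gadd45a, a growth arrest gene, rose by 1.12 ± 0.15 as 1 of 16 p53 targets, or 2 higher and 1 lower adjusted over the list alone, with Aen and Bbc3 chosen after the values were seen, of which Aen passed over all genes with the replicate block at adjusted p = 0.0182 (median -0.020, camera adjusted p = 0.904). Rpl22 (1.36 ± 0.28) was the only 1 of 52 ribosomal protein genes past the threshold in both adjustments (median 0.0085, camera adjusted p = 0.904). Of 14 circadian genes 0 passed in limma in either adjustment and 4 had an unadjusted p under 0.05 (median 0.14, camera adjusted p = 0.812), with Nr1d1 at -0.59 ± 0.16 (other probe 0.085, adjusted p = 0.0445 with the replicate block, and 0.0445 to 0.244 over the alternatives) and Nr1d2 at 0.58 ± 0.19. Of 16 immediate early genes 0 passed in either adjustment and 2 had an unadjusted p under 0.05 (median 0.055, camera adjusted p = 0.812), with Ier3 at -0.38 ± 0.16 and Etv4 at -0.78 ± 0.35 (adjusted p = 0.0489 with the block, and 0.0489 to 0.436 over the alternatives). Txnip, a glucose-responsive gene that inhibits thioredoxin, had a change of -1.28 ± 0.49 (adjusted p = 0.153), which passed with the block (adjusted p = 0.0127, and 0.0127 to 0.334 over the alternatives). The Txnip change ranged from -1.62 to -0.82 over the fits without 1 array and was as small as -0.76 under the other settings. The probes of Ftl1 and Rpl22 were dim for their lists, at 4.88 and 6.28 log2 units in control arrays. The median levels of these lists were 10.7 and 13.4. Gclc passed in 1, Rpl22 in 3, Ftl1 in 5, and Gadd45a in all of the 8 fits without 1 array, with adjusted p of up to 0.116. For 8 lists without a call, namely fatty acid oxidation, hepatocyte identity, urea cycle, p53 targets, ribosomal proteins, immediate early genes, AMPK subunits and mitochondrial biogenesis, the median, the mean and the test's direction differed in sign.

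Markers of other liver cell types had medians of different sign. All 15 sinusoidal endothelial markers had higher values with metformin, of which 1, the nuclease gene Dnase1l3 (1.14 ± 0.14), rose in both adjustments (median 0.49, camera adjusted p = 0.0266; adjusted p = 0.927 with an estimated correlation). The brightest of them, Egfl7, chosen after its value was seen, had means of 9.45 and 9.88 log2 units and did not pass. Dnase1l3 was dim, at 4.84 log2 units in control arrays, near the lower end of the scale, and 5.97 in metformin arrays. With the replicate block 5 endothelial markers were higher (adjusted p of the list = 0.000258). This list lost its call without control replicate 1 (adjusted p = 0.197), metformin replicate 2 (0.107) or metformin replicate 4 (0.216), and its adjusted p was 0.000196 to 0.967 over the alternatives. Its median was 0.25 without control replicate 1 and 0.23 without metformin replicate 4, and reached 0.72 among the fits without 1 array. The number of endothelial markers past the threshold was 3 without metformin replicate 1. Among 4 measured cholangiocyte markers, 3 of which also stand in the dedifferentiation list, Cldn4 (claudin 4, 1.30 ± 0.18) rose over all genes, or 2 higher and 0 lower adjusted over the list alone, with Sox9 chosen after the values were seen (median 1.01, camera adjusted p = 0.0110; adjusted p = 0.207 with an estimated correlation), and 2 were higher with the block. With the endothelial score as a covariate the cholangiocyte median was 0.46 (adjusted p = 0.0460, and 0.00226 to 0.0460 over the alternatives). The cholangiocyte mean was highest in metformin replicates 4 (0.92) and 2 (0.80), as was the endothelial mean (0.90 and 0.69). Of 13 macrophage markers 0 passed in limma in either adjustment and 0 had an unadjusted p under 0.05 (median -0.12, camera adjusted p = 0.471), with C1qc at -0.79 ± 0.37 and C1qb at -0.55 ± 0.32, and with the block 2 were lower, C1qc among them (adjusted p = 0.0398, and 0.0398 to 0.438 over the alternatives). Of 13 stellate cell markers 0 passed in either adjustment and 2 had an unadjusted p under 0.05 (median 0.10, camera adjusted p = 0.812), with Reln at 0.39 ± 0.13 and Lox at 0.85 ± 0.33 (adjusted p = 0.0481 with the block, 0.0388 without control replicate 1, and 0.0388 to 0.319 over the alternatives). The 6 lymphocyte and neutrophil markers had 0 past it in either adjustment and 0 at an unadjusted p under 0.05 (median -0.15, camera adjusted p = 0.711), and Ms4a1 (-0.41 ± 0.35) and Nkg7 (-0.22 ± 0.22) lay near the lower end of the scale. Dnase1l3 and Cldn4 passed in all 8 fits without 1 array.

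**Figure D3:**
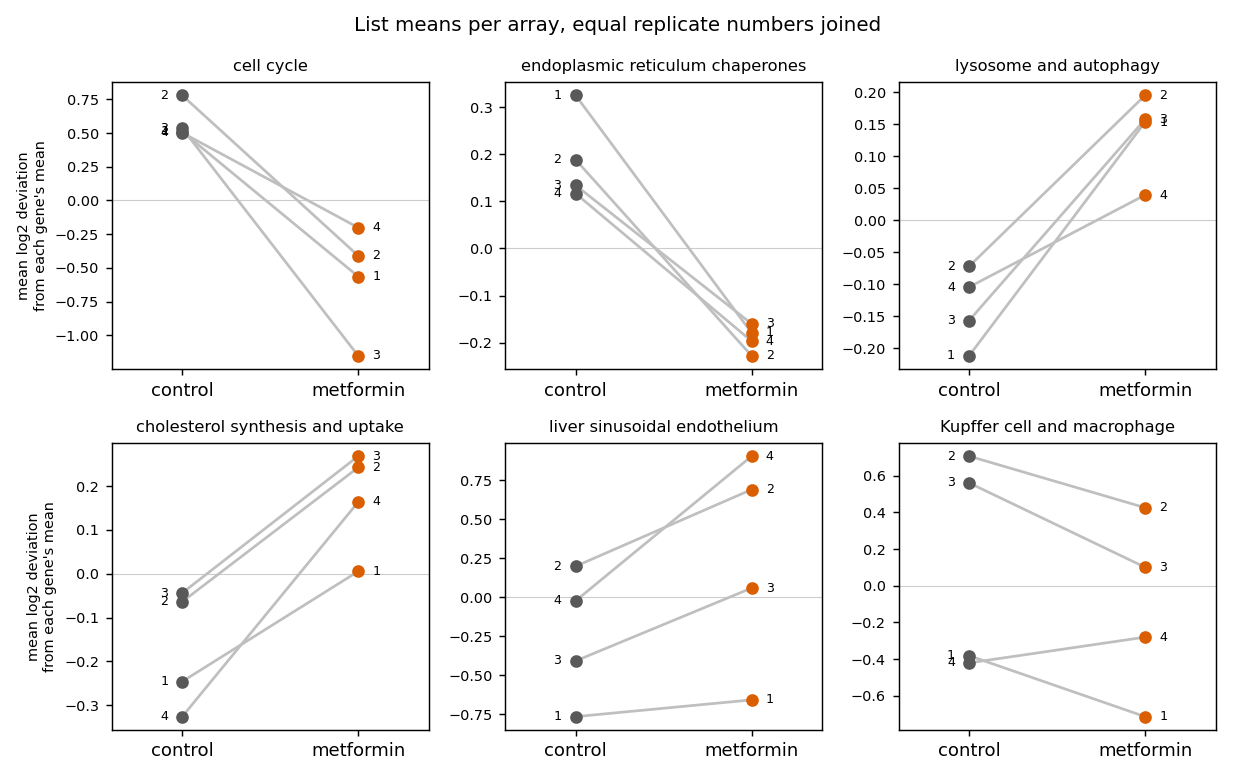
Mean log2 deviation of the members of 6 lists from each gene's mean over all arrays (y axis), for control (grey) and metformin (orange) arrays, with equal replicate numbers joined by lines and each panel on its own range. The cell cycle means run from 0.50 to 0.78 in control and from -1.15 to -0.20 in metformin arrays, while the endothelial and macrophage means of the groups overlap.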

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

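The tests of the cell cycle pattern were chosen after the result was seen, and the count over splits of the arrays was not. Of 274 groups of 4 arrays, taken over the named genes and the list means, 18 had 1 array set apart from the other 3 by more than Dixon's 95% limit, where chance gives about 1 group in 20. Control replicate 1 was the array set apart in 6 of them.

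Among genes that changed, the array set apart was, in log2 units, metformin replicate 4 at 5.87 against 7.27 to 7.39 for Plin4, control replicate 4 at 5.06 against 5.91 to 5.96 for Vil1, control replicate 3 at 9.99 against 9.35 to 9.45 for Nudt18 and metformin replicate 2 at 5.09 against 4.59 to 4.65 for Fbp2. For Rrm2 it was control replicate 2 at 9.73, the highest control, and metformin replicate 3 at 5.92, the lowest metformin array. For the histone probes H2ac22 and H2ac15 it was control replicate 1 at 10.05 against 11.30 to 11.49 and control replicate 1 at 9.67 against 10.74 to 10.91. It was control replicate 1 at 9.24 against 9.36 to 9.38 for Polr1a, metformin replicate 3 at 13.32 against 12.72 to 12.82 for Cldn4 and metformin replicate 1 at 8.16 against 9.24 to 9.36 for Rsad2. Among genes that did not pass the threshold it was control replicate 2 at 6.13 against 4.35 to 4.47 for Ms4a1, control replicate 1 at 5.34 against 4.29 to 4.45 for Nkg7, control replicate 1 at 5.32 against 4.34 to 4.37 for G6pc, metformin replicate 1 at 5.41 against 5.75 to 5.81 for Trib3 and control replicate 1 at 13.10 against 12.21 to 12.30 for Cxcl1. The acute phase list had metformin replicate 1 at 0.52 against -0.29 to -0.23 in its mean deviation, and the cell cycle list had control replicate 2 at 0.78 against 0.50 to 0.54.

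The 1003 probes unnamed here entered no comparison above. With every probe tested by itself, 29 of them were higher and 28 lower with metformin.

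With the pairing left aside, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many as 740 genes. That is 2.86% of the splits, the smallest share that 35 splits can give. The highest of the others gave 4, a split of replicates 1 and 4 from replicates 2 and 3. Only 8 of the splits part all 4 pairs of equal replicate number, as the real one does. These are too few for a share under 0.05, and besides the real one with 740 they gave 0 genes. With the numbers taken as pairs, the splits therefore cannot exclude chance.

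Lower cell cycle transcripts could come from a smaller share of non-parenchymal cells, which divide in culture, or from 1 control array. If the dividing cells carried their markers in proportion, a smaller share would lower these by about as much. The lowest median of the macrophage, endothelial and stellate lists was -0.12, against -1.17 for the cell cycle. This gap was beyond the SD of the changes of the marker genes, which does not measure the spread between arrays. Between arrays the mean of the macrophage markers had an SD of 0.60 in control and 0.49 in metformin arrays. That of the endothelial markers had an SD of 0.43 and 0.70. The brightest markers, chosen after their values were seen, were Dcn (11.08 and 11.21 in control and metformin arrays), Lyz2 (a change of -0.52 ± 0.39 to 9.48 in metformin arrays) and Egfl7 (9.45 and 9.88). The stellate list was dim, with a median level of 5.43, so many of its members had little room to fall. The values go against fewer macrophages or endothelial cells as the whole source but, with 4 arrays per group, do not exclude it. Nor do they exclude a loss of dividing cells that carry little of these markers. Without control replicate 2 the cell cycle median was -1.09, so that array did not carry the difference, and over all alternatives the median was -1.39 to -0.75. What stays open, and was not tested, is whether fewer cells of any type were cycling or each cycling cell held less of these transcripts, which a count of cells in S phase would separate.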

How the results depend on the processing

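The tests with the endothelial marker score and of list members without single arrays were chosen after seeing the data. Cell cycle, endoplasmic reticulum chaperones, ribosome biogenesis, cholesterol synthesis, lysosome and cholangiocyte lists passed camera in each of the 8 fits without 1 array and in the 11 other refits, but not with an estimated correlation. Of the 740 genes, quantile normalization kept 737 among its 750 and median centring 740 among its 742, since the arrays nearly shared a distribution. Gene counts lay between 364 and 483 higher and between 375 and 446 lower under the other settings, except a 1.5-fold minimum (278 and 287) and array weights (606 and 583, of which 737 genes were shared with the 740 of the fit without weights). With every probe tested by itself, 443 probes were higher and 477 lower. Leaving out 1 array gave 70 to 401 higher and 100 to 393 lower genes, with fewer samples in each fit. The counts fell most without metformin replicate 3 (70 and 104) and metformin replicate 2 (79 and 100). Of the 67 named genes past the threshold, 32 passed it without any 1 array and 35 lost it without at least 1. The replicate block gave 483 higher and 446 lower genes, 613 of them also called without it, and it changed no call of a named gene or list other than those given with the results. Lists called higher numbered 7, but 6 with the lowest 25% of genes left out and with the endothelial score, 4 with the block, 4 with the lower 50% of genes left out, 3 by fry, 0 with an estimated correlation and 4 to 8 without 1 array. Lists called lower numbered 3, but 0 with an estimated correlation, 2 by fry and 3 to 4 without 1 array. Gluconeogenesis (adjusted p = 0.236), the stress response (0.0708) and the endothelium (0.225) were lost with the lower 50% left out, and the stress response (0.0568) also with the lowest 25%. Among named genes, Actg1 was lost with loess, trend and robust settings, every probe and the endothelial score, Amotl2 with trend and robust settings, Polr1a with the mean of its probes, and Ddit4, Cxcl10, Il1b, Rsad2, Hal and Gclc with the endothelial score. Foxa2, Cox7b, Ccl2, Nr1d1, Nr1d2, Atp5g1 and Pklr passed under at least 1 filter, variance, weight, offset or score setting. By fry the cholesterol, lysosome, cholangiocyte, cell cycle and chaperone lists passed. The cause was not tested where not stated. Signal over background is unknown and limits the dim genes.

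Except for the endothelium, the results that changed sign had not been called. Ribosomal proteins did so with quantile (-0.018) and loess normalization (-0.015). With the lower 50% of genes left out, glycolysis was at -0.044, bile acid genes at 0.26 and immediate early genes at -0.0042. With the mean of a gene's probes, fatty acid oxidation was at -0.023, the circadian clock at -0.048 and mitochondrial biogenesis at 0.057. With array weights, interferon genes were at -0.0042, urea cycle at 0.013, p53 targets at 0.078, Srebf1 at -0.032 and Atf4 at 0.030. With the endothelial score as a covariate, complex I was at 1.0e-05, complexes II to V at 0.023, acute phase at 0.29, bile acid at 0.084, urea cycle at 0.11, p53 at 0.077, immediate early genes at -0.047, mitochondrial biogenesis at 0.0023 and Acaca at 0.11. The endothelial list itself, a called list, was then at -0.063, by construction, and fatty acid synthesis was called (adjusted p = 0.0153), while the stress response list was not (adjusted p = 0.273).

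Over the fits without 1 array, medians that changed sign ranged from -0.032 to 0.13 for fatty acid oxidation, -0.072 to 0.017 for complex I, -0.057 to 0.0025 for complexes II to V, -0.29 to 0.17 for acute phase, -0.056 to 0.061 for bile acid, -0.059 to 0.083 for urea cycle, -0.060 to 0.033 for p53, -0.043 to 0.061 for immediate early, -0.012 to 0.29 for interferon, -0.0087 to 0.11 for hepatocyte identity, -0.13 to 0.062 for NRF2, -0.020 to 0.023 for ribosomal protein, -0.058 to 0.056 for mitochondrial biogenesis, -0.046 to 0.18 for stellate, -0.40 to 0.042 for macrophage, -0.0068 to 0.16 for fatty acid synthesis, -0.095 to 0.17 for glycolysis and -0.19 to 0.033 for NF-kB genes. Among genes the ranges were -0.33 to 0.021 for Nkg7, -0.18 to 0.39 for Ppargc1a, -0.50 to 0.17 for Acaca, -0.58 to 0.014 for Ms4a1, -0.085 to 0.16 for Srebf1, -0.11 to 0.10 for Atf4 and -0.18 to 0.10 for Pdk4.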

Other observations

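The gene families here were defined by their symbols after the leading genes had been seen, the genes named from them were chosen after their values were seen, and the tests of the lysosomal and endothelial patterns were chosen after the results were seen. Among 33 families, 1 was higher and 6 were lower by camera. Their directions held under quantile, median and loess normalization, which could hardly change them, since the arrays nearly shared a distribution. No family was tested with the replicate block or without single arrays. Among the members counted as lower, the histone gene H2az1 and the splicing genes Srsf9 and Sf3b3 did not pass with the block (adjusted p = 0.0523, 0.0546 and 0.0669). Of 44 histone genes 14 fell and 0 rose (adjusted p = 1.25e-08; adjusted p = 0.343 with an estimated correlation), a family of near-identical copies. Centromere proteins had 6 of 13 lower, among them Cenpa, the histone variant of the centromere (-1.52 ± 0.34), and Cenph (-1.45 ± 0.21) (adjusted p = 8.07e-07; adjusted p = 0.343 with an estimated correlation). Condensin and cohesin had 4 of 14 lower, Ncapd2, Ncapg2, Ncapd3 and Ncaph2, whose probes ran from -0.83 to 0.16 (adjusted p = 0.000571), replication factors 5 of 25, Orc6, Rfc5, Pole, Cdc45 (-1.07 ± 0.23) and Gins3, which had an adjusted p of 0.0507 with the replicate block (adjusted p of the family = 0.000879), and kinesins 7 of 23 lower and 1 higher (adjusted p = 0.0454). Splicing proteins, which serve all cells, had 7 of 43 lower and 0 higher, led by Hnrnph1 (-1.05 ± 0.14) (adjusted p = 2.23e-05). With an estimated correlation none of the 7 passed, and the smallest adjusted p of any family was 0.314.

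Single genes of other families, chosen after their values were seen, rose in families that camera did not call. Besides Cldn4 and Cldn1, Cldn2 rose by 0.89 ± 0.19 (3 of 12 claudins, adjusted p of the family = 0.223), and Gjb2, the connexin 26 gap junction protein, rose by 1.28 ± 0.18. Of 6 sirtuins, NAD-dependent deacylases, 3 rose, which were Sirt5 (1.39 ± 0.20), Sirt1 (0.58 ± 0.14) and Sirt2 (0.42 ± 0.11), and the family was not called (adjusted p = 0.112). Neither Sirt1 nor Sirt2 passed with the replicate block (adjusted p = 0.0609 and 0.0745).

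Higher values of the lysosome and autophagy list could come from more macrophages or endothelial cells, which are rich in lysosomes, in the metformin wells. The macrophage markers had a median of -0.12, below the lysosome list's 0.33 by more than the SD of the changes of the marker genes. The brightest of these markers, Lyz2, chosen after its value was seen, had a change of -0.52 ± 0.39 and a mean of 9.48 in metformin arrays. Between arrays, however, the mean of the macrophage markers had an SD of 0.60 in control and 0.49 in metformin arrays. It was higher with metformin in 1 of 4 pairs. These values go against more macrophages but, with 4 arrays per group, do not exclude them. With the endothelial score as a covariate the lysosome median was 0.27 and the list stayed called (adjusted p = 0.00332, but without the score adjusted p = 0.207 with an estimated correlation), which argues against endothelial cells as the whole source. Proton pump subunits outside the fixed list were higher too, with a camera adjusted p of 0.00476 (0.343 with an estimated correlation). Past the threshold were 3 of 14, Atp6v0a1 (1.06 ± 0.15, other probe 0.16), Atp6v1g1 (0.66 ± 0.14) and Atp6v1d (0.59 ± 0.14). Whether these genes rose in the hepatocytes themselves stays open, since the arrays hold no values per cell type, and transcripts measured in sorted hepatocytes would decide it.

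The endothelial markers may reflect endothelial cells that remained among the hepatocytes in amounts that differ from well to well. Within groups these markers varied together, with a mean pairwise correlation of 0.61, and 0 of 1000 random lists of matched level reached it, their 95th percentile being 0.091. The macrophage markers gave 0.51 and the stellate markers 0.22. By the same measure the acute phase list gave 0.40, the cell cycle list 0.39 and the p53 targets -0.025. Random lists share no regulation, so these values cannot tell content that varies between wells from genes regulated together. Within the pairs of equal replicate number the endothelial mean was higher with metformin in 4 of 4, by 0.11 to 0.93, and the list had an adjusted p of 0.000258 with the replicate block, but, without the block, adjusted p = 0.927 with an estimated correlation. Whether metformin changed that content is open, since 4 pairs are too few for a test of signs to pass 0.05, and without the block the list was called only with some arrays.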
